A study of Mus musculus with 42 samples.

How the data were processed

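Total RNA from 42 mouse samples had been hybridised to Illumina expression BeadChips, 1 array per sample. Per the labels' protocols, RNA was extracted with a miRNeasy kit and checked on a Bioanalyzer, and biotinylated cRNA was made with an Ambion MessageAmp kit. Growth conditions and the composition of the differentiation cocktail are not given in the sources used here. The samples fell into 20 groups per the labels: embryonic stem (ES) cells and the GPSC-A and GPSC-B lines, each untreated (day 0) and after 2, 7, 14, 21 and 28 days of embryoid body culture (2 arrays per group), and primary hepatocytes of E16 embryos and of postnatal day 1 (PN1) mice (3 arrays per group).

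The main values were the deposited scanner table, which gives per array and probe a signal intensity on a linear scale, not normalised between arrays per the file headers, and a detection p-value. GenomeStudio is named in the submitters' processing notes, with a version not given in the sources used here. The detection p-values deposited by the authors compare a probe with the negative controls of its array. The deposited series matrix holds the authors' processed signal of the same arrays. It lies on a linear scale with column medians of 133.31 to 133.34, and it ranked the probes of each array as the scanner table did (rank correlation 1). The method of that normalisation is not given in the sources used here, so the matrix served only as an alternative. No other columns of per-sample values were left unused.

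The table held 45281 probes. The platform annotation gave 1 gene symbol to 34885 of them, several to 18 and none to 10378, and a probe with several or none was named nowhere. Gene numbers and an updated gene table changed 0 of the symbols. A probe was kept when its detection p was under 0.01 on at least 2 arrays, which left 19251 probes, 2846 of them without a single symbol. Where several kept probes shared a symbol, the one with the highest mean over all arrays stood for the gene, giving 10879 genes. Signals were background corrected by normexp with the detection p-values, quantile normalised and set to log2 with an offset of 16 (neqc of limma 3.58.1 in R 4.3.3). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Other probes of a called gene can differ from the one used. Among 2159 such probes in the ES comparison of day 28 with day 0, 1124 were called the same way, 10 the opposite way and 1025 not at all. For PN1 against E16, 1396 such probes gave 692, 11 and 693.

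Between 8427 and 15123 probes per array (18.6 to 33.4%) were detected at p under 0.01. Median scanner signals ran from 109 to 158, with all 6 hepatocyte arrays at 109 to 115. The PN1 arrays detected 8427 to 9287 probes and the E16 arrays 9882 to 11539. Log2 values of replicate arrays correlated at 0.950 to 0.982 across genes. The highest correlation between arrays of different groups was 0.986. The number of arrays limits the precision of each value, and signals near the negative controls carry no order.

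One linear model with the 20 groups was fitted per gene to all arrays (lmFit and eBayes of limma, 22 residual degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. Adjusted p-values of genes below are from this limma model, and an error after ± beside a log2 change is the standard error of the fit. The labels do not say that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. A probe not detected on any array of one group has only a bound there. Its fold is printed as "at least N-fold", the mean of the detected group against, per array, the higher of the lowest detected signal and the probe's own. In list medians with undetected members at their bounds, a member counted as 0 where it was detected in neither group or its bound was under 1-fold.

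A set of 32 gene lists covering hepatocyte programmes, embryonic and germ lineages, other cell types of liver, and general programmes held 1078 entries and 994 different genes, of which 979 had a probe and 717 were tested. Lists were tested with camera of limma at a preset correlation of 0.01 between genes, and again with a correlation estimated from the data. Adjustment was over the lists of a comparison. Members were counted from the adjustment over all genes and again adjusted over the list alone. Genes named for a comparison were drawn from those meeting a rule. It took the 10 largest rises and 10 largest falls among called genes detected in both groups (unnamed gene models left out). It also took the 5 largest bounds each way among genes undetected in 1 group and detected on all arrays of the other. Up to 4 called members of each list, and 20 anchor genes whatever their result, completed it. Only part of these genes are printed, and the tested anchors Sox17, Col1a1 and Actc1 are not. Of the anchors, Foxa2, Tat, Tdo2, G6pc and Cyp7a1 missed the detection filter and Hbb-b1 had no listed probe. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

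Alternatives were the series matrix, no background correction, scaling to a common median in place of quantile normalisation, no detection filter and a stricter one, every probe tested alone, a fit on the groups of a contrast alone, a variance trend with robust moderation, the replicate number as a block, each array left out in turn, Spearman in place of Pearson correlations, and the estimated correlation of camera. Added after the data were seen were a block of replicate number within lines, fits without hepatocyte arrays or without blood genes, and the change correlations between lines. The set called blood genes held the erythroid, leukocyte and megakaryocyte lists and every gene called higher in PN1 than in E16, whatever its cell type.

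The labels number the replicates, so pairing by number was checked through correlations of deviations from group means. Same-numbered arrays of a line deviated together in each of the 15 pairs of days. The correlations were 0.246 to 0.381 in ES, 0.438 to 0.643 in GPSC-A and 0.326 to 0.591 in GPSC-B. The numbers thus mark a deviation shared within a line, which the main model leaves out and the block within lines takes up. Whether it came from paired cultures or from array processing cannot be told. Between lines the 108 pairs ran from -0.038 to 0.56 with a median of 0.255, so deviations were partly shared, but not in every pair, and the numbers were not taken as pairs. The first arrays of ES and GPSC-B had median scanner signals of 133 to 154 and 138 to 157, the second ones 116 to 125 and 116 to 124, and in GPSC-A they were 146 to 158 and 136 to 157. Between E16 and PN1 the 3 pairs ran from 0.00589 to 0.0816 (median 0.0764), and the numbers do not pair samples there.

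The procedure was tested on simulated arrays with known changes in 67, 67 and 66 of 10879 genes (1.5-fold, 2-fold and 4-fold). For GPSC-A day 28 against day 0, 5.97%, 11.9% and 72.7% of them were called, with 0 unchanged genes called. For PN1 against E16 the shares were 2.99%, 25.4% and 84.8%, with 3 unchanged genes called. A shifted list was called in each simulation and 0 others were. Simulated values were drawn independently, without the shared deviations between genes and between same-numbered arrays. The simulations therefore do not show how often unchanged genes or lists are called where such deviations are present.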

Results

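Genome-wide transcript levels were measured on 42 arrays to follow mouse pluripotent cells through hepatic differentiation. The cells were embryonic stem (ES) cells and GPSC-A and GPSC-B, where GPSC stands for germline cell-derived pluripotent stem cells. Each was profiled untreated and on days 2, 7, 14, 21 and 28 of embryoid body culture with a hepatic differentiation cocktail, with 2 arrays per group. Primary hepatocytes of E16 fetuses and of PN1 pups, 3 arrays each, served as reference. Of the 10879 genes tested, the first 2 principal components carried 36.4% and 26.8% of the variance. The first set hepatocytes apart from cultured cells and the second followed the days of culture.

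**Figure D1:**
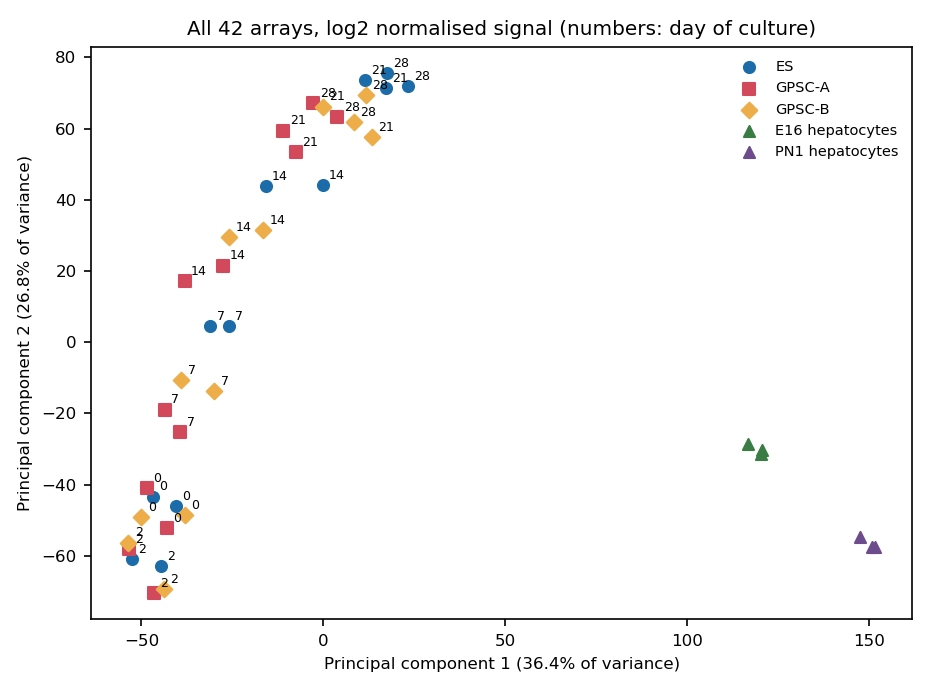
Each point is 1 of the 42 arrays, placed by the first (x axis, 36.4% of variance) and second (y axis, 26.8% of variance) principal components of log2 normalised signal, with color for cell type and small numbers for the day of culture. The hepatocyte arrays lie at the right, and the cultured arrays climb along the second axis from days 0 and 2 to days 21 and 28.

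The change over 28 days of culture was examined first. Several core pluripotency genes fell steeply in all 3 lines (n = 2 arrays per group). Pou5f1, the transcription factor Oct4, changed by -7.98 ± 0.53 (log2 ± SE) in ES, -7.34 ± 0.53 in GPSC-A and -7.46 ± 0.53 in GPSC-B. Esrrb, an orphan nuclear receptor of naive pluripotency, changed by -8.80 ± 0.58, -5.94 ± 0.58 and -7.13 ± 0.58. Zfp42 (Rex1) ended at least 57.9-fold, 18.6-fold and 41.9-fold lower, undetected at day 28 in each line. Dnmt3l, a DNA methyltransferase cofactor, was at least 381-fold lower in ES and changed by -7.36 ± 0.63 and -7.10 ± 0.63 in the GPSC lines. Nanog changed less in GPSC-A, by -2.53, which became -1.41 without the second day 0 array. Of the 31 measured members of the pluripotency list, 28 fell in ES, 27 in GPSC-A and 27 in GPSC-B, while 0, 1 and 0 rose. Adjusted over the list alone, 29, 27 and 27 fell. The list median was -4.35, -4.39 and -4.41, or -4.15, -4.22 and -4.22 with undetected members at their bounds (camera adjusted p = 1.1e-05, 1.5e-05 and 9.6e-06 with an estimated correlation). The cell cycle list fell as well, with 28, 30 and 29 of 37 members lower and 1, 0 and 1 higher (adjusted p = 4e-04, 0.00023 and 2e-04 with an estimated correlation). Among them Mcm5, a subunit of the replicative helicase, changed by -4.38 ± 0.34, -4.26 ± 0.34 and -4.71 ± 0.34. In the germline list 11, 8 and 11 of 22 members fell and 2 rose in each line (adjusted p = 0.011, 0.013 and 0.01 with an estimated correlation), among them the meiotic cohesin Rec8, at least 4.94-fold, 4.09-fold and 3.42-fold lower.

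Part of the fetal liver secretory programme rose by day 28. Apoa1, the main apolipoprotein of HDL, was undetected at day 0 and ended at least 17.3-fold higher in ES, 9.86-fold in GPSC-A and 14.4-fold in GPSC-B. Serpina1b, an alpha-1-antitrypsin, rose at least 27.3-fold, 13-fold and 11.6-fold, and Vtn, which encodes vitronectin, at least 12.3-fold, 8.44-fold and 9.1-fold. Transferrin (Trf) rose by 3.52 ± 0.81, 4.12 ± 0.81 and 3.56 ± 0.81 on the log2 scale, the kininogen Kng1 by 3.36 ± 0.45, 3.95 ± 0.45 and 4.04 ± 0.45, and Dlk1, an imprinted surface protein of hepatoblasts, by 5.66 ± 0.42, 6.35 ± 0.42 and 6.93 ± 0.42. The haemoglobin-binding plasma protein Hp rose at least 330-fold, 171-fold and 127-fold. Outside the secreted proteins, the enzyme Hsd11b1, which regenerates active glucocorticoid, rose at least 476-fold, 116-fold and 327-fold. Alb, encoding albumin, and Afp (alpha-fetoprotein) were detected on 0 arrays of any line at day 0 or 28, which leaves no fold to give. The 1 Alb probe read only 7.67 in E16 hepatocytes, whose arrays had lowest detected signals of 6.18 to 6.74. Its lack of detection in culture therefore does not show that albumin transcripts were absent. Cps1, the first enzyme of the urea cycle, was detected on 0, 1 and 1 of the day 28 arrays and the transcription factor Hnf4a on 0, 0 and 2. Their changes of 0.90 ± 0.51 and 0.06 ± 0.51 (Cps1 in GPSC-A and GPSC-B) and 0.65 ± 0.41 (Hnf4a in GPSC-B) were not called. Of the 30 measured members of the hepatoblast and fetal secreted protein list, 15 rose in ES, 13 in GPSC-A and 16 in GPSC-B, while 0, 1 and 0 fell and the others did not pass. Its median was 1.11, 0.43 and 1.45, or 0.51, 0.02 and 0.95 with undetected members at their bounds. The GPSC-A median became 0.75 without the second day 0 array and 0.90 without the first day 28 array. At the preset correlation the list was called in each line, and adjusted p = 0.06, 0.056 and 0.022 with an estimated correlation. Coagulation and complement genes had 12, 8 and 10 of 30 members higher and 0 lower (adjusted p = 0.087, 0.18 and 0.092 with an estimated correlation, none passing). Their median was 0.31, 0.31 and 0.59, and 0 in each line with undetected members at their bounds. It became 0.47 in ES without the second day 0 array, 0.21 and 0.18 in GPSC-A without the first day 0 or day 28 array, and 0.36 in GPSC-B without the first day 28 array.

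Lists of later hepatocyte function were not called in any line by camera at the preset correlation. In the perinatal and adult hepatocyte list 6, 4 and 4 of 21 members rose and 1 fell in each line (adjusted p = 0.12, 0.33 and 0.45). For the cytochrome P450 list 5, 4 and 4 of 16 rose and 0, 0 and 1 fell (adjusted p = 0.1, 0.33 and 0.3). Cyp2f2, a P450 of airway and liver, rose at least 27.4-fold, 4.7-fold and 38.5-fold, and Cyp2d22 at least 14.4-fold, 19.1-fold and 29-fold. Urea cycle and amino acid catabolism genes gave 3 rises in each line and 2, 3 and 3 falls among 18, with Arg1, the last enzyme of the cycle, at 4.18 ± 0.46 in ES and at least 2.82-fold and 7.25-fold higher in GPSC-A and GPSC-B. The fitted GPSC-A change of Arg1, 2.44, became 1.48 without the first day 28 array. Hepatocyte transcription factors gave 5, 6 and 5 rises and 1, 1 and 2 falls among 18 (adjusted p = 0.24, 0.14 and 0.08). Among these, Foxa1, a pioneer factor of endoderm, rose by 2.83 ± 0.48 in ES and at least 6.69-fold and 5.75-fold in the GPSC lines. Gluconeogenesis and glycogen genes gave 3, 2 and 2 rises and 0 falls among 9, fatty acid oxidation genes 7, 5 and 5 rises and 2, 1 and 0 falls among 19, and lipoprotein and cholesterol genes 5, 3 and 3 rises and 1, 3 and 1 falls among 23.

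Genes of other lineages rose beside the liver genes. In the fibroblast, stellate cell and matrix list 26, 22 and 22 of 35 members rose and 1 fell in each line, or 26, 24 and 25 rises adjusted over the list alone (adjusted p = 0.0066, 0.021 and 0.022 with an estimated correlation). Lum, a matrix proteoglycan, rose at least 138-fold, 47.4-fold and 40.9-fold. In the keratin and surface ectoderm list 11, 8 and 9 of 15 members rose and 1, 2 and 2 fell (adjusted p = 0.06, 0.28 and 0.092 with an estimated correlation), with Krt14, a keratin of basal epidermis, up by 5.73 ± 0.46, 4.38 ± 0.46 and 5.60 ± 0.46. Among 16 cholangiocyte genes 8, 7 and 9 rose and 1, 2 and 2 fell (adjusted p = 0.075, 0.18 and 0.092 with an estimated correlation), Krt19 by 3.83 ± 0.35, 2.20 ± 0.35 and 4.04 ± 0.35. Cardiac muscle gave 14, 8 and 8 rises and 1, 0 and 1 falls among 21 (adjusted p = 0.075, 0.39 and 0.34 with an estimated correlation), including the atrial light chain Myl4 at 4.96 ± 0.51, 3.23 ± 0.51 and 3.81 ± 0.51. Leukocyte and Kupffer cell genes gave 9, 2 and 4 rises and 0, 1 and 1 falls among 28, called in ES alone at the preset correlation (adjusted p = 0.22 with an estimated correlation). In ES the complement subunits C1qb and C1qc of macrophages ended at least 45.9-fold and 57.2-fold higher. The fitted change of C1qb was 2.20 in GPSC-A and 2.29 in GPSC-B, and that of C1qc 2.75 in GPSC-B. These became 0.645, 0.305 and 0.734 without the first day 28 array of the line, and 3.75, 4.27 and 4.77 without the second. Visceral endoderm and yolk sac genes gave 11, 8 and 8 rises and 3, 4 and 3 falls among 22, again called in ES alone at the preset correlation (adjusted p = 0.085 with an estimated correlation). In the hypoxia and glycolysis list 10, 11 and 10 of 22 members rose and 2, 0 and 2 fell. It was called in the GPSC lines at the preset correlation (adjusted p = 0.041 in GPSC-A and 0.092 in GPSC-B with an estimated correlation), and in ES it was not (adjusted p = 0.087). In GPSC-A the keratin median was 1.63, or 0.28 with undetected members at their bounds, and the cardiac median 0.33, or 0. At the preset correlation the keratin call of GPSC-A ended without the first day 28 array (median 0.99), and the cardiac call without the second (median 0.21). Both ended on the series matrix and without background correction, and the keratin call in a fit on its own groups. A call in one line and not in another does not show that the lines differ.

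For the remaining lists, ES, GPSC-A and GPSC-B are given in that order. Imprinted genes gave 13, 11 and 8 rises and 1, 3 and 3 falls among 29, called in ES at the preset correlation (adjusted p = 0.075 with an estimated correlation). Smooth and skeletal muscle gave 7, 6 and 8 rises and 3, 3 and 1 falls among 16, called in GPSC-B (adjusted p = 0.19 with an estimated correlation). Stress response genes gave 6, 8 and 13 rises and 4, 1 and 3 falls among 27, called in GPSC-B (adjusted p = 0.25 with an estimated correlation). That last call ended with replicate number as a block within lines (adjusted p = 0.071), with median scaling, without the first day 0 array (median 1.25) and without the second day 28 array (median 1.05). The other lists were not called at day 28 in any line. Primitive streak genes gave 3, 3 and 2 rises and 1 fall each among 14, erythroid genes 1, 2 and 2 rises and 4, 4 and 5 falls among 28, and megakaryocyte genes 3, 1 and 2 rises and 2, 0 and 2 falls among 12. Endothelial genes gave 6, 3 and 4 rises and 3, 3 and 6 falls among 24, neural genes 2, 5 and 7 rises and 7, 4 and 4 falls among 21. Gut and stomach genes gave 2, 1 and 2 rises and 0, 1 and 0 falls among 12, and trophoblast genes 3, 2 and 3 rises and 2, 4 and 5 falls among 14. Ribosomal protein genes gave 1 rise each and 2, 1 and 1 falls among 42, and oxidative phosphorylation genes 4, 1 and 6 rises and 1, 0 and 0 falls among 44. At day 28, counts adjusted over the list alone differed from those over all genes by at most 4 members of a list.

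Across all genes, 1886 rose and 1796 fell in ES by day 28, 1662 rose and 1469 fell in GPSC-A, and 1830 rose and 1652 fell in GPSC-B. Scaling arrays to a common median gave 1139 rises and 1531 falls in ES, 1385 rises and 696 falls in GPSC-A and 997 rises and 1447 falls in GPSC-B, with the median of all genes moved to 0.18 and -0.11, and to -0.15 in ES. GPSC-A counts fell to 2017 on the series matrix and 1995 without background correction, and GPSC-B counts to 2284 and 2252.

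**Figure D2:**
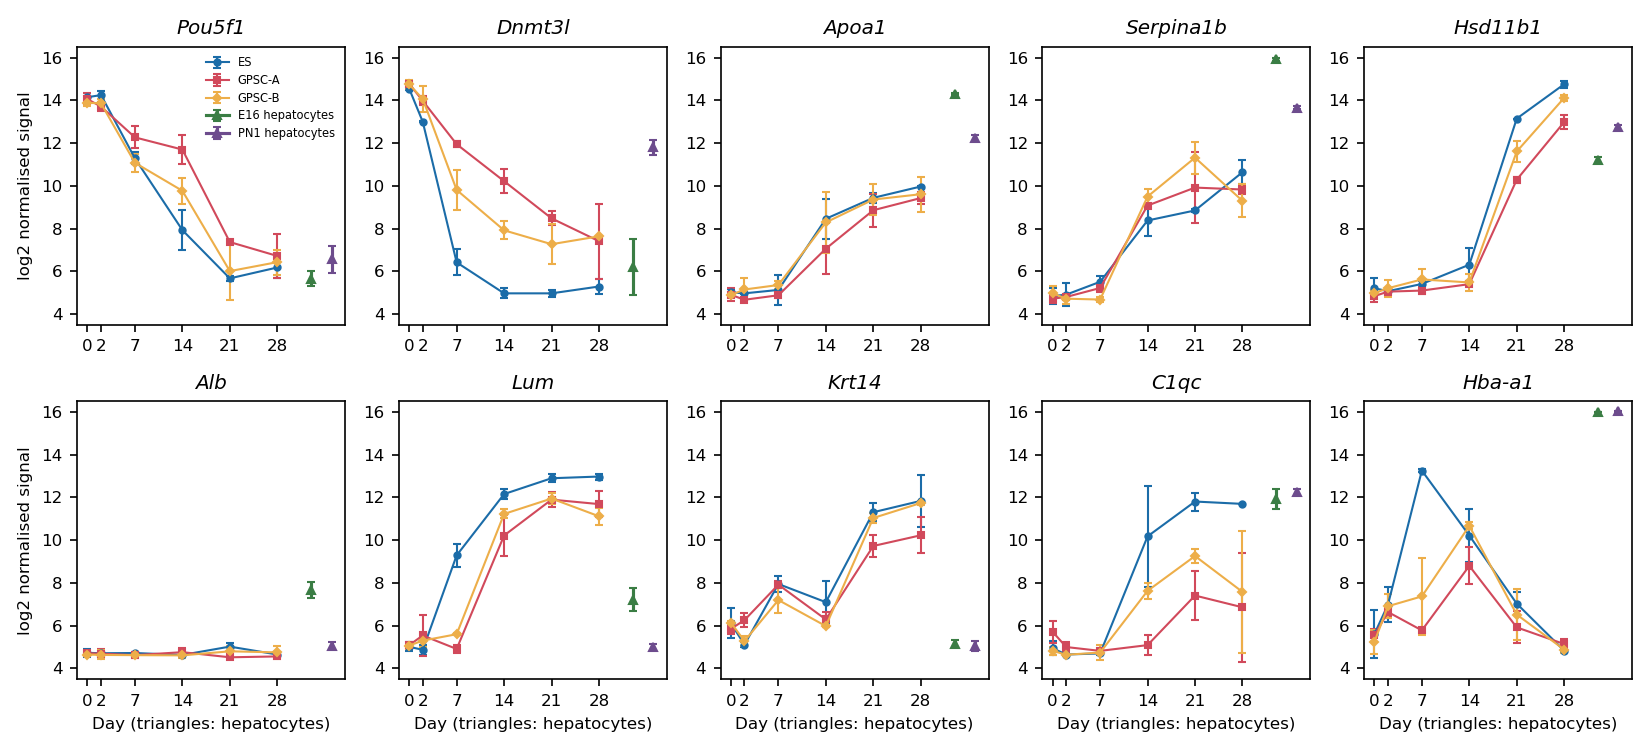
Log2 normalised signal (y axis) of 10 genes by day of culture (x axis) as group means with SD bars, in ES, GPSC-A and GPSC-B (n = 2 arrays) and in E16 and PN1 hepatocytes (triangles, n = 3 arrays). Pou5f1 and Dnmt3l fell, Apoa1, Serpina1b, Hsd11b1, Lum and Krt14 rose, and Hba-a1 peaked on days 7 to 14. Alb stayed undetected in culture, by a probe that read only 7.67 in E16.

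The path between the end points was traced at days 2, 7 and 14. On day 2 smooth muscle and matrix genes fell, while Pou5f1 gave 0.09 ± 0.53, -0.35 ± 0.53 and -0.03 ± 0.53 in ES, GPSC-A and GPSC-B with no call. Growth conditions of the untreated cells are not given in the sources used here. It cannot be told whether the stem cells themselves lost the muscle and matrix transcripts. Acta2, smooth muscle actin, changed by -6.15 ± 0.30, -5.53 ± 0.30 and -5.83 ± 0.30, and Lox, which crosslinks collagen, by -6.24 ± 0.42, -5.21 ± 0.42 and -5.49 ± 0.42. In the smooth and skeletal muscle list 7, 6 and 6 of 16 members fell and 0 rose (adjusted p = 0.0077, 0.0017 and 0.00095 with an estimated correlation). In the fibroblast list 16, 15 and 11 of 35 members fell and 0 rose, or 17, 17 and 13 falls adjusted over the list alone (adjusted p = 0.0052, 0.00034 and 0.01 with an estimated correlation). Without the first day 0 array the smooth muscle median of ES, -0.58, became -1.01, and the fibroblast median of GPSC-B, -0.55, became -0.996, or -0.318 without the second. In ES 13 of 31 pluripotency genes had fallen by then and 2 had risen (adjusted p = 0.0052 with an estimated correlation, median -1.07, or -0.60 without the second day 2 array), among them Klf4 at -5.21 ± 0.48 and Tfcp2l1 at -4.53 ± 0.59, both factors of the naive state. Fgf5, a marker of the primed epiblast, rose by 2.79 ± 0.51 in ES. Genes called were 280 higher and 593 lower in ES, 62 and 259 in GPSC-A, and 19 and 161 in GPSC-B. With median scaling they were 27 and 504 in ES, 8 and 81 in GPSC-A and 0 and 62 in GPSC-B, with the median of all genes at -0.36 in ES and 0.12 in GPSC-A. Fitted on their own groups, ES gave 202, GPSC-A 19 and GPSC-B 0 called genes by limma, which gave 933 genes at an unadjusted p under 0.05 for GPSC-B in the full model. Acta2 and Lox of GPSC-B kept their folds in that fit, at an adjusted p of 0.0608 each, and were not called. Leaving out the second day 2 array gave 470 in ES, 190 in GPSC-A and 61 in GPSC-B. Leaving out the first or second day 0 array gave 208 or 202 in GPSC-A, and the second gave 55 in GPSC-B. A block of replicate number within lines gave 294 in GPSC-B. The series matrix and no background correction gave 496 and 484 in ES, and the latter 206 in GPSC-A.

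By day 7 primitive streak and definitive endoderm genes were high. In GPSC-A and GPSC-B 9 and 11 of the 14 measured members rose, or 11 and 13 adjusted over the list alone, and in ES 6 or 7 (adjusted p = 4e-07, 1.1e-06 and 0.002 with an estimated correlation). Lhx1, a homeobox gene of head organiser and mesendoderm, rose at least 85.6-fold in GPSC-A and 79.3-fold in GPSC-B and by 4.44 ± 0.65 in ES. Gsc, encoding goosecoid, rose at least 14.2-fold and 19.1-fold in the GPSC lines, and Eomes at least 4.28-fold and 4.49-fold. In ES 12 of 28 erythroid genes rose and 1 fell (adjusted p = 0.0017 with an estimated correlation). The embryonic globins Hba-x and Hbb-bh1 rose at least 71.2-fold and 69.7-fold, and Hba-a1 by 7.65 ± 0.64. In the endothelial list 11 of 24 members rose and 0 fell in ES (adjusted p = 0.002 with an estimated correlation), including the junction genes Cldn5 and Cdh5, at least 16.2-fold and 6.09-fold. Its median of 0.97 became 1.54 and 0.61 without the first and second day 7 array, and the erythroid median of 0.27 became 0.47 without the first day 0 array. Isl1, a factor of heart field progenitors, rose by 5.97 ± 0.37 in ES, 3.22 ± 0.37 in GPSC-A and 4.16 ± 0.37 in GPSC-B. Genes called at day 7 were 837 higher and 855 lower in ES, 476 and 445 in GPSC-A, and 645 and 648 in GPSC-B. Median scaling gave 362 and 578 in ES and 291 and 143 in GPSC-A, with 743 called in GPSC-B, and medians of all genes of -0.12, 0.27 and 0.11. Counts fell to 490 in GPSC-A without the second day 0 array, to 565 or 608 without the first or second day 7 array, and to 816 in GPSC-B without the second day 7 array. The series matrix gave 1024, 504 and 791, no background correction 998, 499 and 771, and fits on their own groups 440 in GPSC-A and 670 in GPSC-B.

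On day 14 the first secreted liver proteins had appeared. Serpina1b stood at least 5.71-fold, 7.78-fold and 13.3-fold above day 0 in ES, GPSC-A and GPSC-B, and Vtn at least 5.43-fold, 6.96-fold and 6.54-fold. Dlk1 had risen by 6.28 ± 0.42, 5.66 ± 0.42 and 7.13 ± 0.42, and Gata6, a factor of primitive and definitive endoderm and heart, at least 30.7-fold and 9.28-fold in ES and GPSC-A and by 4.80 ± 0.50 in GPSC-B. In ES 15 of 24 endothelial genes rose and 0 fell (adjusted p = 0.0035 with an estimated correlation), as did 14 of 21 cardiac genes (adjusted p = 0.027 with an estimated correlation), among them Myl3 by 5.74 ± 0.56. Hepatoblast list members rose in 11, 8 and 13 of 30 cases and fell in 1, 2 and 1 (adjusted p = 0.2, 0.23 and 0.051 with an estimated correlation). Called genes numbered 1401 higher and 1200 lower in ES, 1093 and 866 in GPSC-A, and 1275 and 1137 in GPSC-B. On day 21 they numbered 1843 and 1671, 1510 and 1272, and 1605 and 1534. With median scaling the split was 1093 to 231 in GPSC-A on day 14, and 1033 to 1481 in ES and 1484 to 438 in GPSC-A on day 21, with the median of all genes at 0.32, -0.19 and 0.28. Under that scaling 1498 genes were called in ES and 1510 in GPSC-B on day 14. GPSC-A gave 1295 on day 14 without its second day 0 array. For both days the series matrix and uncorrected values gave fewer calls by more than 1.5 times in each line.

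**Figure D3:**
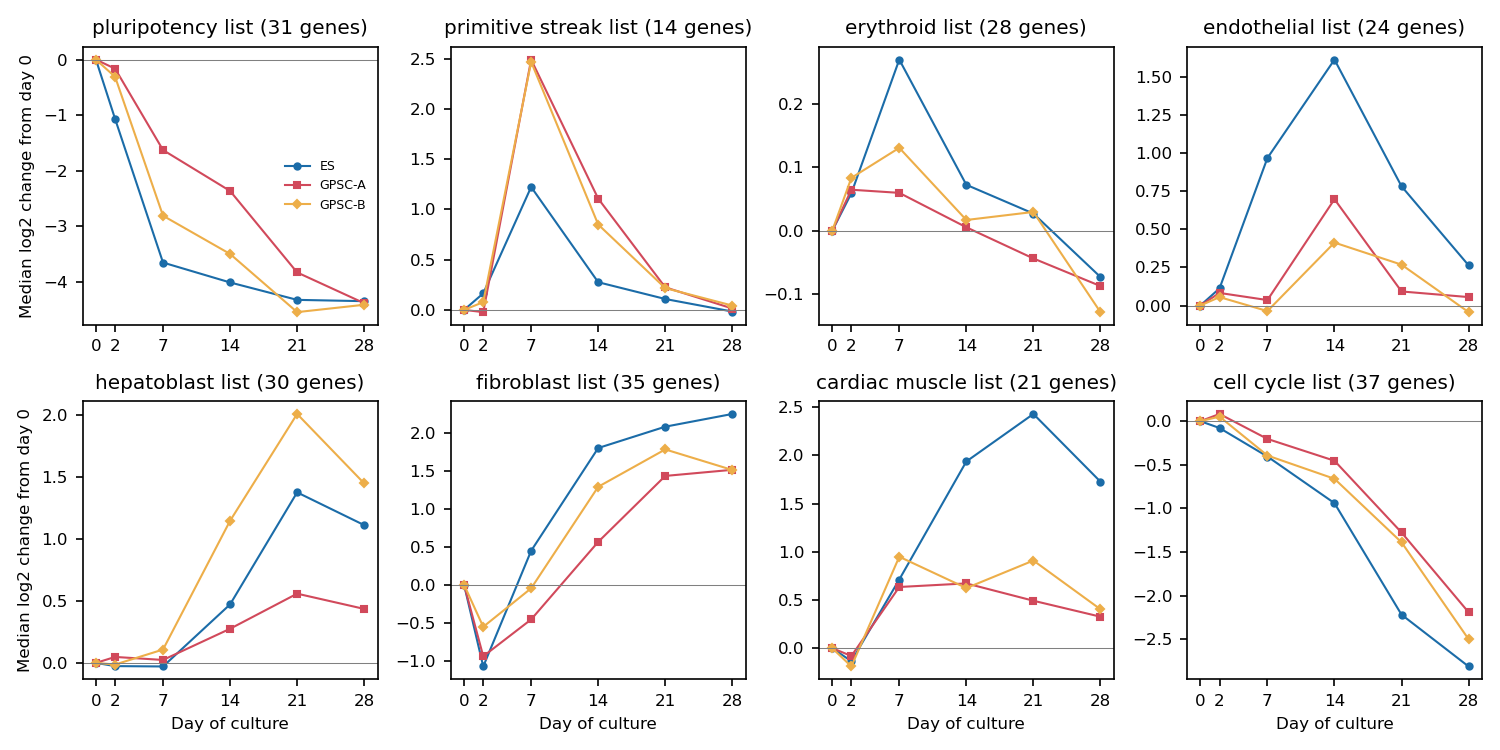
Median log2 change from day 0 (y axis) of the measured genes of 8 lists by day of culture (x axis) in ES, GPSC-A and GPSC-B, each value a median over genes of the fitted group differences, undetected genes included at their fitted values. Primitive streak genes peaked on day 7, endothelial genes on day 14 in ES, and pluripotency and cell cycle genes were lowest on days 21 or 28.

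The samples labelled PN1 hepatocytes were compared with those labelled E16 hepatocytes (n = 3 arrays each). The PN1 arrays detected 8427 to 9287 probes and the E16 arrays 9882 to 11539, and the contrast does not separate stage from the makeup or quality of the preparations. Liver secretory genes were lower in the PN1 samples. Afp was at least 7.94-fold lower, Ttr, which encodes transthyretin, at least 8.34-fold, and Cps1 at least 33.6-fold, each undetected on every PN1 array. Alb was at least 1.43-fold lower, measured at 7.67 ± 0.39 in E16 (log2 signal ± SD) and undetected in PN1. Apoa1 changed by -2.05 ± 0.43 (log2 ± SE), Trf by -2.87 ± 0.66 and the fibrinogen chain Fga by -3.72 ± 0.41. The keratin gene Krt18 differed by -5.99 ± 0.45, and Krt8 and Krt19 were at least 37.9-fold and 15.2-fold lower. Of 30 hepatoblast genes 27 were lower and 0 higher, with a median of -3.10, or -2.93 with undetected members at their bounds. Coagulation genes were lower in 25 of 30 cases and higher in 0, with a median of -2.68, or -1.98 at the bounds (adjusted p = 1e-04 with an estimated correlation for both lists). In the cytochrome P450 list 11 of 16 members were lower and 2 higher, in the urea cycle list 12 of 18 and 0, in the lipoprotein list 15 of 23 and 0, and in the cholangiocyte list 10 of 16 and 2 (adjusted p = 0.00025, 0.0013, 0.0036 and 0.019 with an estimated correlation). Hepatocyte transcription factors had 10 of 18 lower and 1 higher, and visceral endoderm genes 14 of 22 and 0 (adjusted p = 0.0016 and 0.0013 with an estimated correlation). Adjusted over the list alone, 1 or 2 members of the urea cycle, lipoprotein and transcription factor lists were higher. The perinatal and adult list, which holds genes that normally gain expression around birth, had 13 of 21 members lower and 4 higher (median -1.28, or -1.24 at the bounds, adjusted p = 0.074 with an estimated correlation). Hnf4a differed by -0.27 ± 0.34 (adjusted p = 0.61).

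Leukocyte genes moved the other way in the same samples. Of 28 leukocyte and Kupffer cell genes 15 were higher in PN1 and 0 lower, with a median of 1.30, or 1.26 at the bounds (adjusted p = 0.019 with an estimated correlation). Spi1, the PU.1 factor of myeloid cells, was higher by 2.42 ± 0.30, the Kupffer cell receptor Vsig4 by 2.21 ± 0.26, and Chil3, a chitinase-like protein of macrophages, by 4.48 ± 0.20. Slc7a11, the cystine transporter, was higher by 3.93 ± 0.55, Igfbp2 by 3.45 ± 0.26 and Dnmt3l by 5.59 ± 0.51. Among erythroid genes 2 of 28 were higher and 1 lower, among megakaryocyte genes 2 of 12 and 0, among endothelial genes 1 of 24 and 4, and among fibroblast genes 1 of 35 and 10. Of these only the fibroblast list was called at the preset correlation (adjusted p = 0.32 with an estimated correlation), a call that ended without the first PN1 array (median -0.23), with median scaling and without background correction. Of 29 imprinted genes 10 were lower and 1 higher (adjusted p = 0.04 with an estimated correlation). The lower ones included Peg3 at -5.53 ± 0.26, Dlk1 at -4.32 ± 0.34 and Grb10 at -3.25 ± 0.27. The imprinted list median of -0.21 was 0 with undetected members at their bounds, 13 members being detected in neither group. The fitted median became -0.40, -0.33 and -0.10 without the first, the second and the third E16 array. Fatty acid oxidation had 6 of 19 members lower and 2 higher, hypoxia 9 of 22 and 2, and cell cycle 1 of 37 lower and 4 higher (adjusted p = 0.062, 0.15 and 0.29 with an estimated correlation, none passing). At the preset correlation the fatty acid call ended without the first or second E16 array or the first PN1 array (medians -0.49, -0.40 and -0.42), and the cell cycle call without the first or second E16 array or the third PN1 array (0.29, 0.33 and 0.28). In total 1120 genes were higher in PN1 and 1468 lower. Median scaling gave 300 higher and 1355 lower, with the median of all genes at -0.17, the series matrix gave 1504 calls and no background correction 1468.

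**Figure D4:**
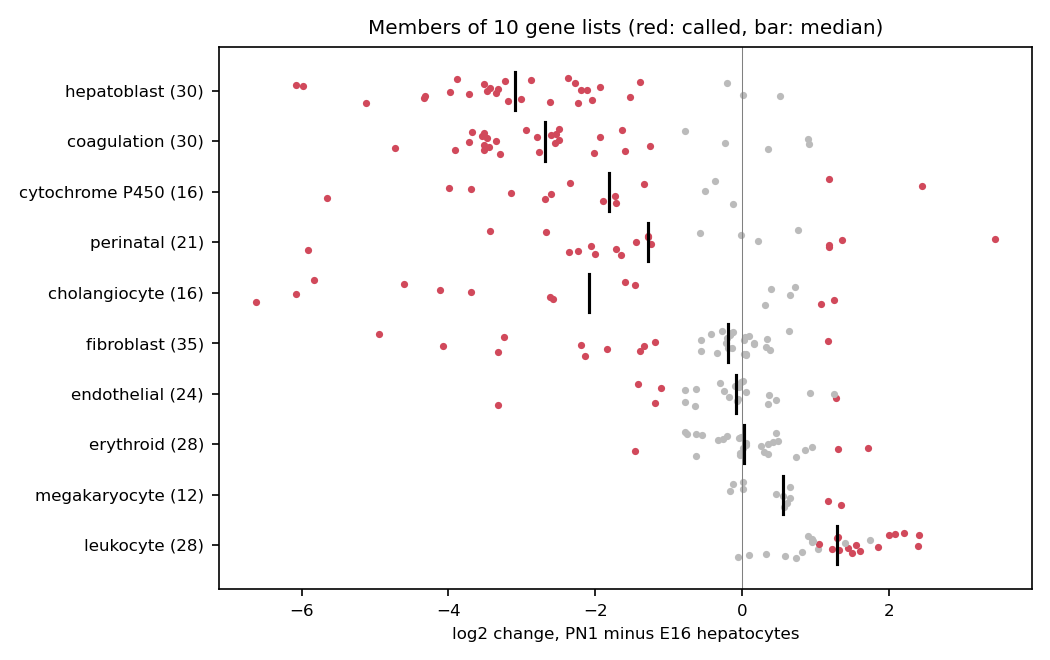
Each point is a measured gene of 1 of 10 lists (y axis, number of genes in brackets), placed by its log2 difference PN1 minus E16 (x axis, n = 3 arrays per group), with red for called genes and a bar at the list median. Hepatoblast and coagulation genes lie mostly below 0, leukocyte genes mostly above 0, and erythroid genes around 0.

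Day 28 cells were then set against the primary hepatocytes. Against E16 the secreted liver proteins remained far lower. Apoa1 differed by -4.33 ± 0.49 in ES, -4.88 ± 0.49 in GPSC-A and -4.70 ± 0.49 in GPSC-B, Trf by -5.06 ± 0.74, -4.70 ± 0.74 and -5.21 ± 0.74, and Apoa2 by -5.48 ± 0.56, -7.58 ± 0.56 and -7.14 ± 0.56. Alb was at least 3.24-fold, 3.53-fold and 3.24-fold lower, Afp at least 18-fold, 19.6-fold and 18-fold, and Gnmt, a methyltransferase of mature liver, at least 64.8-fold, 70.4-fold and 64.7-fold. Hepatoblast genes were lower in 25, 27 and 26 of 30 cases and higher in 1 each (median -4.39, -4.74 and -4.78, or -4.30, -4.38 and -4.26 at the bounds). The perinatal and adult list had 15, 16 and 16 of 21 members lower and 3, 1 and 1 higher (adjusted p = 0.0013, 0.00047 and 0.00034 with an estimated correlation), and hepatocyte transcription factors 10, 12 and 11 of 18 lower and 3, 2 and 4 higher (adjusted p = 0.0039, 0.0043 and 0.0087 with an estimated correlation), the latter with a GPSC-B median of -1.52 that became -0.91 without the first day 28 array. Blood genes were lower too, with 26 of 28 erythroid genes lower and 0 higher in each line. Hba-a1, adult alpha globin, was at least 1050-fold, 1140-fold and 1050-fold lower, and the neutrophil peroxidase Mpo at least 231-fold, 252-fold and 231-fold. Leukocyte genes were lower in 20, 26 and 26 of 28 cases and higher in 0 (adjusted p = 0.00099, 0.00014 and 0.00018 with an estimated correlation). Matrix genes were higher, 27 of 35 in each line with 1 lower (adjusted p = 0.00098, 0.00082 and 0.00082 with an estimated correlation). The collagenase Mmp2 differed by 7.75 ± 0.35, 7.81 ± 0.35 and 7.90 ± 0.35, and Thy1, a surface protein of mesenchymal cells, was at least 108-fold, 68.7-fold and 88.2-fold higher. Krt14 was at least 38.9-fold, 12.8-fold and 36.3-fold higher. Counts against E16 were 2188 higher and 1725 lower for ES, 2090 and 1664 for GPSC-A, and 2054 and 1560 for GPSC-B. Median scaling gave 2745 and 810, 3270 and 779, and 2903 and 790, with the median of all genes at 0.44, 0.65 and 0.57. On the series matrix GPSC-A gave 2467 calls and GPSC-B 2395.

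Against PN1, matrix genes were higher, while liver lists did not move alike. Apoa1 differed by -2.28 ± 0.49, -2.83 ± 0.49 and -2.65 ± 0.49, the ES call being lost with median scaling. Alb and Afp were undetected on the PN1 and the day 28 arrays alike, so no difference is given. Gnmt was at least 27.5-fold, 29.9-fold and 27.5-fold lower. Hepatoblast genes were lower in 20, 21 and 20 of 30 cases and higher in 5 each (median -2.09, -2.06 and -2.33, or -1.98, -1.96 and -1.99 at the bounds, adjusted p = 0.088, 0.085 and 0.084 with an estimated correlation). Coagulation genes were lower in 17, 17 and 16 of 30 cases and higher in 4, 3 and 3 (adjusted p = 0.068, 0.033 and 0.035 with an estimated correlation), and perinatal and adult genes in 10, 11 and 10 of 21 and 4, 2 and 2 (adjusted p = 0.088, 0.033 and 0.035 with an estimated correlation). Urea cycle genes were lower in 5, 7 and 6 of 18 cases and higher in 1, 2 and 2 (adjusted p = 0.094, 0.037 and 0.045 with an estimated correlation). Their medians were -0.47 and -0.51 in the GPSC lines. With median scaling they were 0.05 and 0.16, still below the median of all genes, which then stood at 0.98 and 0.86. Without the first day 28 array the GPSC-A median of -0.47 became -0.74, and without the second that of GPSC-B, -0.51, became -0.21. The perinatal and adult median of GPSC-B, -0.79, became -1.47 without the first. Not called were transcription factors, with 6, 4 and 3 of 18 lower and 3, 5 and 5 higher, cytochrome P450 genes, with 5, 7 and 6 of 16 and 4, 5 and 4, and fatty acid oxidation genes, with 4, 5 and 4 of 19 and 6, 3 and 4. Cholangiocyte genes were higher in 10, 9 and 10 of 16 cases and lower in 2 each (adjusted p = 0.088, 0.18 and 0.14 with an estimated correlation). Leukocyte genes were lower in 24, 28 and 28 of 28 cases and erythroid genes in 26 each, with 1 erythroid gene higher in ES. Dlk1 was higher by 6.37 ± 0.38, 6.93 ± 0.38 and 6.75 ± 0.38, Timp1, an inhibitor of matrix proteases, by 7.60 ± 0.35, 7.75 ± 0.35 and 7.96 ± 0.35, and Krt19 at least 10.6-fold, 6.79-fold and 8.88-fold. Fibroblast genes were higher in 30 of 35 cases in each line and lower in 1, 0 and 1 (median 4.46, 3.69 and 3.33, or 2.41, 2.75 and 2.98 at the bounds, adjusted p = 0.0023, 0.003 and 0.0031 with an estimated correlation), and imprinted genes in 20, 16 and 16 of 29 and lower in 0, 3 and 2 (adjusted p = 0.0023, 0.033 and 0.045 with an estimated correlation). Counts were 2705 higher and 2075 lower for ES, 2680 and 2148 for GPSC-A, and 2672 and 1999 for GPSC-B. Median scaling gave 4134 and 708, 4823 and 687, and 4411 and 704, with the median of all genes at 0.74, 0.98 and 0.86.

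Whole profiles were compared by Pearson correlation across the 10879 genes, which are not independent replicates. Day 28 arrays correlated with the mean E16 profile at 0.786 ± 0.006 in ES, 0.775 ± 0.015 in GPSC-A and 0.787 ± 0.004 in GPSC-B (SD, n = 2 arrays), and with the mean PN1 profile at 0.710 ± 0.008, 0.692 ± 0.008 and 0.706 ± 0.005. The PN1 arrays behind that mean had lower hepatoblast genes (median -3.10) and higher leukocyte genes (median 1.30) than the E16 arrays. The correlation with E16 minus that with PN1 was 0.076 ± 0.0026, 0.083 ± 0.0066 and 0.081 ± 0.0011. Untreated cells already showed a difference of 0.068 ± 0.0042, 0.068 ± 0.0024 and 0.070 ± 0.0049, at correlations of 0.746, 0.749 and 0.748 with E16. E16 arrays correlated at 0.892 ± 0.006 with the PN1 mean (n = 3 arrays). The gene changes from day 0 to day 28 correlated with the difference between E16 and untreated cells of another line at 0.478 in ES, 0.393 in GPSC-A and 0.437 in GPSC-B, and with the corresponding PN1 difference at 0.400, 0.309 and 0.358. Untreated cells are subtracted on both sides, so a loss of pluripotency genes alone raises these values. No cell type other than hepatocytes was compared, so they do not show a move towards hepatocytes in particular. Between lines the changes correlated at 0.809 (GPSC-A and ES), 0.858 (GPSC-B and ES) and 0.912 (GPSC-B and GPSC-A), with no array shared by the values compared.

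**Figure D5:**
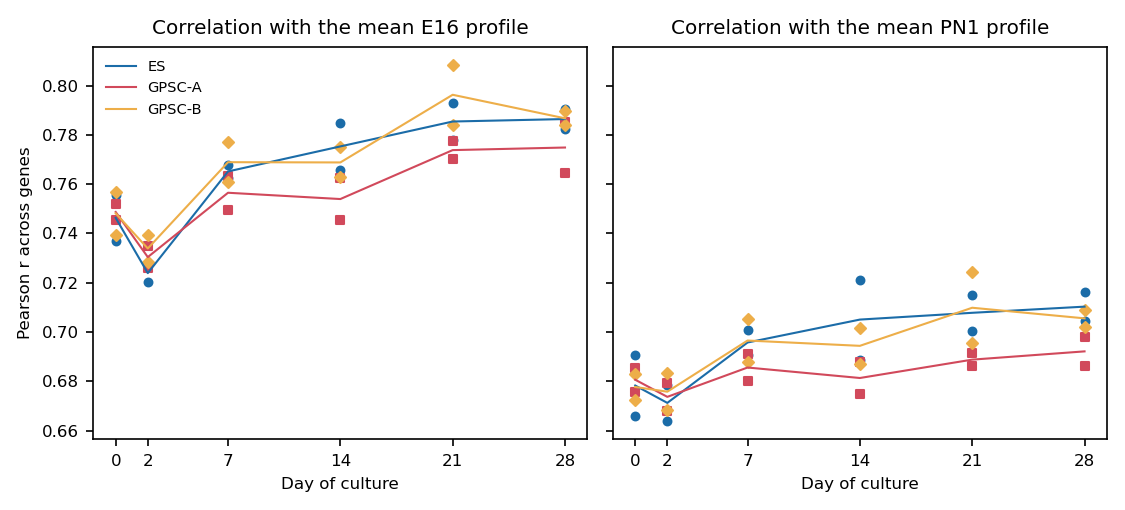
Pearson correlation across 10879 genes (y axis) of each cultured array with the mean E16 profile (left) and the mean PN1 profile (right) by day of culture (x axis), with points for arrays and lines through group means (n = 2). Correlations with E16 were above those with PN1 on every day, day 0 included.

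The GPSC lines were compared with ES cells before culture. Pou5f1 differed by -0.09 ± 0.53 in GPSC-A and -0.26 ± 0.53 in GPSC-B, with no call. Of 31 pluripotency genes 2 and 2 were higher and 4 and 1 lower, or 7 and 3 lower adjusted over the list alone (adjusted p = 0.083 and 0.83 by camera). Thumpd1, a cofactor of tRNA modification, was higher by 4.48 ± 0.25 and 4.57 ± 0.25, the ribosomal protein gene Rpl29 by 4.14 ± 0.37 and 2.77 ± 0.37, and the mitochondrial ribosomal gene Mrps27 at least 10.2-fold and 8.88-fold. Each value rests on a single probe, and whether these probes read all lines alike was not tested. Usp18 and Oas1g, both interferon-induced, were lower, at -2.95 ± 0.35 and -2.56 ± 0.37 in GPSC-A and -2.88 ± 0.35 and -2.15 ± 0.37 in GPSC-B. Aurkc, a meiotic kinase, was at least 6.29-fold and 8.06-fold lower. Dppa3, a germ cell and pluripotency gene, was higher by 2.73 ± 0.41 and 2.59 ± 0.41, and Xbp1, a factor of the unfolded protein response, by 2.22 ± 0.34 and 2.97 ± 0.34. Germline genes were higher in 2 of 22 cases in both GPSC lines and lower in 3 and 1 (adjusted p = 0.84 and 0.9 by camera). Fibroblast genes were called at the preset correlation with 0 and 1 of 35 members higher (adjusted p = 0.95 and 0.92 with an estimated correlation). Both calls ended without the first ES array (medians 0.27 and 0.38), and that of GPSC-B without its own second array (0.11). In GPSC-A 148 genes were higher and 170 lower, and in GPSC-B 127 and 93. These counts rest on few arrays. GPSC-A gave 211 calls without the first ES array and 134 without its own second array, and GPSC-B gave 128 without the second ES array and 107 without its own second array. Fits on the contrasted groups gave 54 and 51 calls, without Xbp1 in GPSC-A and Oas1g in GPSC-B, and median scaling 125 and 109, the latter as 80 higher and 29 lower. The median of all genes then stood at -0.25 for GPSC-A. With replicate number as a block GPSC-A gave 481 calls. GPSC-B against GPSC-A gave 10 genes higher and 7 lower, among them Trim25 at 3.19 ± 0.48 and Nle1 at -2.65 ± 0.29. That count was 7 without the second GPSC-A array, 11 without the second GPSC-B array (Trim25 at 2.66, no longer called), 1 in a fit on the 2 groups (neither of them) and 27 with every probe tested alone. The split was 9 to 11 on the series matrix and 6 to 11 without background correction, and the median of all genes 0.33 with median scaling.

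At day 28 genes called lower in the GPSC than in the ES cultures included cardiac, endothelial and macrophage genes, though no list passed with an estimated correlation. Myl2, the ventricular light chain, was lower, at -4.69 ± 0.76 in GPSC-A and -5.61 ± 0.76 in GPSC-B, as was Sln (sarcolipin) at -3.78 ± 0.34 and -2.72 ± 0.34. Cardiac genes were lower in 10 and 8 of 21 cases and higher in 0, or 12 and 12 lower and 1 and 1 higher adjusted over the list alone (adjusted p = 0.094 and 0.065 with an estimated correlation). Smooth and skeletal muscle genes were higher in 0 and 6 of 16 cases and lower in 1 and 2 (adjusted p = 0.92 and 0.4 with an estimated correlation). Cldn5, a junction gene of endothelium, was at least 5.81-fold and 5.34-fold lower, with 6 and 6 of 24 endothelial genes lower (adjusted p = 0.099 and 0.065 with an estimated correlation). C1qb was lower, at -4.35 ± 0.84 and -4.30 ± 0.84, calls that ended without the second day 28 array of the GPSC line concerned (-2.80 and -2.32) and, for GPSC-B, in a fit on its own groups. Leukocyte genes were lower in 8 and 7 of 28 cases (adjusted p = 0.099 and 0.43 with an estimated correlation). Visceral endoderm genes were lower in 4 and 4 of 22 cases, Cldn2 at -3.70 ± 0.38 and -3.88 ± 0.38 (adjusted p for the list = 0.084 and 0.06 with an estimated correlation). Higher in the GPSC cultures were Vps35, a retromer subunit, by 6.82 ± 0.48 and 6.86 ± 0.48, Rpl29 by 6.54 ± 0.37 and 5.59 ± 0.37, and Psmd8, a proteasome subunit, at least 48.2-fold and 59.2-fold. These are signals of single probes, which were not tested for reading all lines alike. Egln3, an oxygen-sensing hydroxylase, was at least 2.38-fold and 3.61-fold higher, the GPSC-A call ending without background correction (0.97), and Xbp1 by 2.76 ± 0.34 and 3.94 ± 0.34. In the hypoxia list 3 and 1 of 22 members were higher, and in the stress response list 4 and 4 of 27 (adjusted p = 0.084 and 0.065, and 0.099 and 0.12, with an estimated correlation). Neural genes had 4 and 0 members higher of 21, and the list was called at the preset correlation (adjusted p = 0.18 and 0.57 with an estimated correlation). In GPSC-A its median of 0.75, or 0.19 with undetected members at their bounds, became 0.42 without its own first array. In GPSC-B its median of 0.56 was 0 at the bounds, with 9 members detected in neither group. It became 0.37 and 0.27 without the first and second ES array, 1.01 without its own first array and -0.09 without its own second array. The call ended without either second array and in a fit on its own groups. At the preset correlation the leukocyte call of GPSC-B ended without the same arrays (medians -0.28 and -0.21), and the endothelial call of GPSC-A, at a median of -0.51, without its own first array (-0.26), with -0.31 without its second. The smooth muscle call of GPSC-B, at a median of 0.26, ended without the first ES array (0.23) and without its own first (0.40) or second array (0.14), and without the second ES array the median was 0.57. Of 30 hepatoblast genes 1 and 1 were called higher and 1 and 0 lower, with 8 detected in neither group of each comparison, Alb among them. Apoa1 differed by -0.55 and -0.36 with no call. The total was 310 higher and 500 lower in GPSC-A and 263 and 379 in GPSC-B. GPSC-A gave 433 calls without the second ES array at day 28, 534 on the series matrix, 512 without background correction, 390 with median scaling and 372 in a fit on its own groups. GPSC-B gave 351 calls without the second ES array, 280 without its own second array and 233 in a fit on its own groups. With median scaling it gave 153 higher and 145 lower, and the median of all genes stood at 0.13 for GPSC-A.

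Between the GPSC lines at day 28, 27 genes were higher in GPSC-B and 11 lower, with Ltf (lactotransferrin) at 2.95 ± 0.36, the keratin gene Krt13 at 2.85 ± 0.47 and Fbxo34 at -4.14 ± 0.39. Keratin and surface ectoderm genes were higher in GPSC-B as a list, with 1 of 15 members called and 5 adjusted over the list alone (adjusted p = 0.026 with an estimated correlation). Their median of 0.66 became 0.40 without the first GPSC-B array. Smooth and skeletal muscle genes gave 1 of 16 called and 6 adjusted over the list alone (adjusted p = 0.039 with an estimated correlation), and a median of 0.63, or 0.27 with undetected members at their bounds, that became 0.22 without the second GPSC-B array. A fit on the 2 groups alone gave 0 called genes by limma, against 464 at an unadjusted p under 0.05 in the full model. Median scaling gave 24 and the fit without the first GPSC-B array 25. Krt13 was not called without that array (2.34) or the second GPSC-A array (2.19).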

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

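Of the tests below, the shrinking of the day 0 differences and the interval of the germline list were chosen after the result was seen, as was the comparison with second probes within a line.

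The course from day 0 to day 28 differed between lines by a test of the difference itself (an interaction term in limma). For GPSC-A against ES 403 genes passed, 174 with a more positive change in GPSC-A and 229 with a more negative one. For GPSC-B against ES 184 passed, 70 and 114, and for GPSC-B against GPSC-A 9 passed, 6 and 3. Relative to the change in ES, that of Grb10, an imprinted growth inhibitor, was -2.74 ± 0.47 in GPSC-A and -3.64 ± 0.46 in GPSC-B (log2 ± SE). The GPSC-A call ended with median scaling (-2.22). Cldn2, a claudin of leaky epithelia, differed by -3.56 ± 0.54 and -3.75 ± 0.54, and sarcolipin (Sln) by -4.22 ± 0.48 and -2.83 ± 0.48, the latter not called in a fit on its own groups. Psmd8 gained 3.60 ± 0.50 and 4.12 ± 0.50 more than in ES, and Vps35 4.31 ± 0.68 and 3.98 ± 0.68. Psmd8 was undetected on the ES arrays of day 28, so its gains rest on fitted values near the negative controls. Whether the single probes of these genes read all lines alike was not tested. For Apoa1 no difference in course was called (adjusted p = 0.881 in GPSC-A and 0.991 in GPSC-B).

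Single arrays moved these counts. GPSC-A against ES gave 210 without the first ES array of day 0, 206 without the second ES array of day 28, 202 without its own second array of day 0 and 238 without its own first array of day 28. GPSC-B against ES gave 114 without the second ES array of day 0, 112 without the second ES array of day 28, 299 without its own first and 75 without its own second array of day 28. With replicate number as a block it gave 289. GPSC-B against GPSC-A gave 3 without the second GPSC-A array of day 0, 4 without the first GPSC-A array of day 28, and 5 and 3 without the first and second GPSC-B arrays of day 28. Fits on the contrasted groups gave 128, 20 and 0 calls by limma, where the full model gave 365 genes at an unadjusted p under 0.05 for GPSC-B against GPSC-A. Median scaling gave 123, 56 and 2 calls, the last as 1 more positive and 1 more negative, with the median of all genes at 0.41 for GPSC-A against ES and -0.42 for GPSC-B against GPSC-A.

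Of 318 genes called in GPSC-A against ES at day 0, 124 were called the same way at day 28, and of 220 in GPSC-B 104. Sequence differences between mouse strains under single probes may contribute. Of genes with a second detected probe, 37% in GPSC-A (37 of 100) and 36.5% in GPSC-B (27 of 74) showed at least a 2-fold difference there. Changes within a line gave 57.8% to 67.6%. Those changes were not matched in size to the day 0 differences, so the gap does not decide on sequence differences. A difference in cell state that culture would alter cannot be told apart from sequence differences either. The median ratio of the day 28 to the day 0 difference was 0.4 in GPSC-A and 0.591 in GPSC-B. It was 0.714 and 0.865 over genes higher at day 0, and 0.165 and 0.372 over genes lower there. Choosing genes by their day 0 call also lowers such a ratio. A germline programme expressed as a whole above its level in ES cells is argued against by the germline list medians of -0.09 and -0.13 at day 0 (0 and -0.01 with undetected members at their bounds), whose intervals end at 0.18 and 0.15. Untreated ES cells expressed part of this list, since its median changed by -0.97 in ES by day 28 (-0.45 at the bounds). Expression shared with ES cells is therefore not excluded. Single germline genes, with 2 of 22 called higher in each line, were not excluded, and the strains of the lines were not analysed here.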

How the results depend on the processing

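The block within lines, the fits without hepatocyte arrays or blood genes, and the change correlations between lines were chosen after seeing the data. Of 647 named gene results, 6628 values under the alternatives gave 175 lost calls, 13 gained and 0 reversals, and 2966 values with an array left out gave 138, 8 and 0. Of 229 list results, camera with an estimated correlation ended 58 calls, 2339 values under the other alternatives gave 23 lost and 30 gained calls and 2 reversals, and 1015 with an array left out gave 24, 24 and 1 reversal. The 2 were the urea cycle medians of GPSC-A and GPSC-B against PN1, 0.045 and 0.16 with median scaling. The median of all genes then stood at 0.98 and 0.86, so these lists changed sign but stayed below the other genes. The last was the neural list for GPSC-B against ES at day 28, whose median ran from -0.088 without the second GPSC-B array to 1.006 without the first, fewer arrays being the change made. Calls rest on signal over background, and signals near the detection limit carry folds only as bounds. Counts stayed within 1.5 times with no detection filter, the stricter filter, trend and robust moderation, without hepatocyte arrays and without blood genes. Slide as a block was not run, since the files give no slide. For the values that moved the cause was not tested, except that fits on the contrasted groups hold fewer arrays.

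With the series matrix, calls against day 0 were 496, 1024, 1605 and 2308 in ES at days 2, 7, 14 and 21, 504, 1118, 1720 and 2017 in GPSC-A and 791, 1468, 2024 and 2284 in GPSC-B at days 7 to 28. PN1 against E16 gave 1504, day 28 against E16 2467 (GPSC-A) and 2395 (GPSC-B), and GPSC-A against ES at day 28 534. Without background correction these were 484, 998, 1610 and 2284 in ES, 206, 499, 1119, 1703 and 1995 in GPSC-A from day 2, 771, 1473, 1994 and 2252 in GPSC-B, and 1468 for PN1 against E16. Day 28 against E16 gave 2547, 2413 and 2309, GPSC-A against PN1 3208, and GPSC-A against ES 211 at day 0 and 512 at day 28. Median scaling gave 531, 940 and 1498 in ES (days 2, 7, 14), 89, 434 and 2081 in GPSC-A (days 2, 7, 28), 62, 743 and 1510 in GPSC-B (days 2, 7, 14) and 1655 for PN1 against E16. Against ES it gave 125 and 109 at day 0 and 390 and 298 at day 28, for GPSC-B against GPSC-A 24 at day 28, and for interactions 123, 56 and 2. Fits on the contrasted groups gave 202 (ES day 2), 19 and 440 (GPSC-A days 2 and 7), 0 and 670 (GPSC-B), where limma gave 933 genes at unadjusted p under 0.05 for GPSC-B at day 2. Between lines they gave 54, 51 and 1 at day 0, 372, 233 and 0 at day 28, and 128, 20 and 0 for interactions, with 464 and 365 genes at unadjusted p under 0.05 in the full limma model where GPSC-B against GPSC-A gave 0. Every probe alone gave 27 for GPSC-B against GPSC-A at day 0. With the replicate block, GPSC-A against ES at day 0 gave 481 and the GPSC-B interaction 289, and with the replicate block within lines GPSC-B day 2 gave 294. Of the named results the replicate block made 2 further gene calls and 1 list call and ended 3 list calls. The block within lines made 2 further gene calls and 1 list call and ended 1 list call. Neither block changed another call, and a result can be counted under both.

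With an estimated correlation camera called 4, 5 and 5 lists for day 28 against day 0 (12, 10 and 12 before), 13 for GPSC-A against E16 (23 before), and 0 and 0 for the GPSC lines against ES at day 28 (9 and 11 before). The hepatoblast medians of 1.11 (ES) and 0.43 (GPSC-A) lost their calls. Change correlations with E16 were 0.491 (series matrix), 0.493 (no background correction), 0.522 (median scaling) and 0.469 (no filter) in ES, and 0.422 (no background correction) and 0.355 (Spearman) in GPSC-A. Those with PN1 were 0.410, 0.413, 0.462 and 0.390 in ES, 0.403 with the stricter filter and 0.404 with every probe. In GPSC-A they were 0.330, 0.336, 0.327 and 0.298, then 0.315, 0.316 and 0.286 (Spearman), and in GPSC-B 0.423 with median scaling. Between GPSC-A and ES they were 0.831, 0.836, 0.802 and 0.793, 0.815 with the stricter filter and 0.760 with Spearman. The margin of E16 over PN1 was 0.0541, 0.0588 and 0.0574 with no filter, 0.0791 (ES) and 0.0848 (GPSC-B) with the stricter one, 0.0801 (GPSC-B) with every probe, and 0.0798 (ES) and 0.0833 (GPSC-B) with Spearman.

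Leaving out 1 array at a time, where a lone array is assumed to vary like the other groups, gave for days 2, 7, 14, 21 and 28 counts of 470 to 846, 1166 to 1475, 1923 to 2304, 3015 to 3247 and 3179 to 3453 in ES, 190 to 243, 490 to 746, 1295 to 1710, 2131 to 2513 and 2559 to 2886 in GPSC-A, and 55 to 258, 816 to 1235, 1799 to 2182, 2652 to 2890 and 3005 to 3187 in GPSC-B. PN1 against E16 gave 2431 to 2677. Day 28 gave 3406 to 3940, 3162 to 3835 and 3250 to 3623 against E16, and 4198 to 4759, 4319 to 4804 and 4255 to 4717 against PN1. GPSC-A against ES, GPSC-B against ES and GPSC-B against GPSC-A gave 134 to 282, 107 to 197 and 7 to 23 at day 0, 433 to 595, 280 to 819 and 25 to 38 at day 28, and 202 to 334, 75 to 299 and 3 to 12 for interactions. Pluripotency medians ran from -4.51 to -4.19, -4.53 to -4.02 and -4.59 to -4.29, and hepatoblast medians from 1.09 to 1.44, 0.54 to 0.90 and 1.26 to 1.62. Called lists numbered 12 to 14, 9 to 11 and 12 to 16 at day 28, 13 to 18 for PN1, 17 to 18, 21 to 23 and 20 to 21 against E16, and 8 to 9 and 6 to 11 against ES, the 6 without the second GPSC-B array of day 28. Change correlations were 0.452 to 0.487, 0.335 to 0.426 and 0.375 to 0.468 with E16, 0.371 to 0.409, 0.262 to 0.342 and 0.313 to 0.379 with PN1, and 0.769 to 0.812, 0.796 to 0.872 and 0.857 to 0.905 between lines. The margin of E16 over PN1 was 0.0705 to 0.0826, 0.0781 to 0.0889 and 0.0763 to 0.0877.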

Other observations

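Of the tests below, those of dimmer arrays, of the detection limit, of a uniform share of E16-like cells and of imprints were chosen after the results were seen, as was the interval used in weighing the blood lists.

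Imprinted genes separated the GPSC lines from ES cells by the parental allele normally expressed. At day 28 Grb10 stood at -4.32 ± 0.33 in GPSC-A and -5.08 ± 0.33 in GPSC-B relative to ES (log2 ± SE), the growth inhibitor Cdkn1c at -4.07 ± 0.45 and -3.56 ± 0.45, and the noncoding RNA Meg3 at least 3.62-fold and 3.33-fold lower. The growth receptor Igf2r differed by -1.48 ± 0.32 and -2.35 ± 0.32, the GPSC-A call ending without its first day 28 array (-0.80), with median scaling and in a fit on its own groups. The 9 maternally expressed genes averaged -1.80 and -1.80, with 5 and 6 called lower, against 0.46 and 0.21 for the 14 paternally expressed ones, with 0 called lower and 2 and 0 called higher. Medians of the maternally expressed genes were -1.39 and -1.42, or -1.26 and -1.10 with undetected members at their bounds. At day 0 the averages were -0.97 and -1.06 against 0.08 and 0.02, with medians of -0.47 and -1.28, or -0.34 and -1.28 at the bounds, for the maternally expressed genes. The 3 called lower then in each line were Grb10, Cdkn1c and Meg3. Those Grb10 calls ended in both lines without the first ES array (-1.31 and -1.16), and without the second GPSC-A array (-1.498) and the first GPSC-B array (-1.10). The Cdkn1c call of GPSC-A ended without the second ES array (-1.81) or second GPSC-A array (-1.96), and the Meg3 call of GPSC-B without the first ES array (-1.48) or first GPSC-B array (-1.33). In fits on their own groups 5 of these 6 calls ended, Cdkn1c in GPSC-B being the other, and with median scaling those of Grb10 in both lines and of Meg3 in GPSC-B, the last also on the series matrix and without background correction. A two-sided permutation test over genes with 1e+05 resamples gave p = 4e-05 and 0.00073 at day 28, or 0.00016 and 0.00146 adjusted over the 4 tests, and adjusted p = 0.0034 and 0.00219 at day 0. It describes a difference first noticed in the same data, over clustered genes that are not independent, and says nothing of its origin. Imprints of paternal germ cell origin kept in the GPSC lines are a candidate explanation that cannot be told apart from others. The paternally expressed genes, with both copies then active, should double, and their median at day 28 was 0.36 ± 0.32 and 0.30 ± 0.20 (log2, ± the interval of the median), above 0 but short of that.

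PN1 samples had lower hepatocyte genes and higher leukocyte genes than E16 samples. The leukocyte list, whose median rose by 1.30, does not decide on dimmer arrays or less RNA in the PN1 samples. Quantile normalisation gives each array the same distribution, so a fall of some lists goes with a rise of others. Maturation after birth as the whole cause is argued against by the perinatal and adult list, whose median was -1.28. A larger share of blood cells in the PN1 samples may contribute, since 7 of 7 fitted list medians lay on the side it predicts, though those of endothelial and fibroblast genes were 0 with undetected members at their bounds (5 and 13 members detected in neither group), with the abundant myeloid transcript Lyz2 at 15.75 ± 0.16 against 14.00 ± 0.04 (log2 signal ± SD), a difference of 1.75 that was not called. It cannot be told apart from other causes, because the endothelial (-0.09 ± 0.26), fibroblast (-0.19 ± 0.35) and erythroid (0.03 ± 0.21) medians lay within their intervals and Hba-a1, at 16.03 ± 0.01 and 16.01 ± 0.01, stood at the top of the array scale, where no change can be read. Of the 10 splits of the 6 hepatocyte arrays into 3 and 3, 1 gave as many called genes as the real 2588, the real one itself, and the highest other gave 47, but 10 splits cannot give a share under 0.1.

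At day 28 Apoa1, Trf and other secreted liver proteins were above day 0 while Alb and Afp were undetected. A detection limit could account for the latter if Alb and Afp kept the ratio to E16 that Apoa1 shows, which was not tested. Afp would then stand -0.16, -0.59 and -0.53 log2 units from the lowest detected signal in ES, GPSC-A and GPSC-B, and Alb -2.64, -3.06 and -3.00. With Alb at only 7.67 in E16, a ratio of that size had to put it below that signal. A uniform small share of E16-like cells as the only source of these transcripts is argued against by the spread of hepatoblast members. The SD of their log2 ratio to E16 was 2.97, 2.91 and 2.85 over 15, 16 and 17 members, against a median SE of 0.44, 0.43 and 0.42. Dlk1 stood above E16, by 2.05, 2.61 and 2.43, so such a share beside other expressing cells is not excluded. Endoderm of the visceral or yolk sac kind stays open, with a median change of 1.53 in ES and 0.44 and 0.46 in the GPSC lines over 18 markers outside the hepatoblast list, or 1.03, 0.04 and 0.33 with undetected members at their bounds.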
